A study of Mus musculus with 4 samples.

How the data were processed

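Gene expression was measured on 4 Affymetrix Mouse Expression 430A arrays, each hybridised for 16 hours with 1 biotin-labelled sample. The samples were whole testis of adult W/Wv males, whole testis of adult XX/Sry males, and seminiferous tubules of each genotype. Per the labels, the W/Wv males were a cross of the WB and B6 strains and were bought; the strain of the XX/Sry males is not given in the sources used here, nor is whether whole testis and tubules came from the same animals. For tubules, the tunica was taken off, the testis was digested with collagenase at 5 mg/ml and 37 °C for 40 min, and interstitial cells were removed on a 70 µm strainer.

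The deposited values are array intensity, as MAS5 signals on a linear scale. The submitters' processing notes name MAS5, and the design text of the labels names Microarray Suite 5.0 for scanning and calculation. The mean signal without the lowest and the highest 2% of probe sets was close to 500.2 on each array, so each array had been scaled by its own factor; the scaling target and the detection calls are not given in the sources used here. The deposited signals were used as they stand, and 0 columns of values were left unused. Of 22690 probe sets, 64 controls were set aside and 22626 analysed. The platform's annotation table gave 1 gene symbol to 20380 of them, several to 691 and none to 1555. Of the single-gene probe sets, 20351 had their Entrez identifier in the RefSeq gene table, which changed 0 symbols. This left 12393 genes, 4956 of them with more than 1 probe set. Genes with several probe sets were represented by the one with the highest mean log2 signal. No genome sequence was used, so no coordinates are given beyond chromosomes.

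Each group had 1 array, so folds are ratios of deposited signals between single arrays. An additive fit of genotype and preparation to the log2 signals, with 1 residual degree of freedom, was added after seeing the data and tested with limma 3.58.1 in R 4.3.3 (moderated test, two-sided, with a trend on mean signal, 9.98 prior degrees of freedom, and Benjamini-Hochberg adjustment over 22626 probe sets in each of the 2 comparisons). It takes the 4 arrays as independent and counts interaction as error. Its error is therefore disagreement between the pairs, and holds no spread between animals if both preparations of a genotype came from the same animals. The double ratio is that interaction and was not tested. The genotype comparison took XX/Sry over W/Wv within each preparation, and the preparation comparison tubules over whole testis within each genotype. A probe set passed when it was at least 2-fold different the same way in both pairs, which is the rule in the design text of the labels. The counts were set beside those for independent pairs, computed within 20 bins of mean signal, and beside the counts of opposite directions. A double ratio set the genotype ratio in tubules against that in whole testis, with a threshold of 4-fold and a brighter array at or above its median signal in each preparation. The 27 bacterial control probe sets without a mouse target gave a background bound, their highest signal, of 76.3 in W/Wv whole testis, 63.9 in XX/Sry whole testis, 46.1 in W/Wv tubules and 61.0 in XX/Sry tubules; 71.9%, 71.4%, 75.3% and 69.8% of probe sets lay above it. Where the dimmer of 2 signals lay below the bound of its own array, the fold is given as at least the brighter signal over the higher bound of the pair. No fold is given where the brighter signal did not exceed its own bound, or where that ratio did not exceed 1.

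Gene lists were fixed before the data were examined, as were the comparisons, thresholds, named-gene rule and alternatives, except for 2 alternatives named with their values. Of 478 list symbols, 409 were measured. The 24 lists were Y chromosome genes, X inactivation and escape genes, reference genes, and markers of Sertoli cells, Leydig cells, peritubular myoid and smooth muscle cells, spermatogonia and early germ cells, meiotic germ cells, spermatids, macrophages, lymphocytes, mast cells, endothelial cells, epididymis and efferent ducts, and adipocytes. The others were blood haemoglobin genes, ovarian somatic (granulosa) genes, growth factors and receptors acting on spermatogonia, cholesterol synthesis genes, tight and gap junction genes, immediate early and heat shock genes, interferon response and MHC genes, collagen and matrix genes, and cell cycle genes. Some genes are on more than 1 list, among them Gdnf and Kitl. A list's median log2 ratio was placed among 10000 random lists of the same size and like signal, and called where its percentile was under 2.5 or over 97.5, with at least 4 members measured; this describes the arrays and is no test of genotype, since genes are not replicates. Bootstrap intervals resampled the genes of each list 10000 times on the same arrays. They describe the spread among genes and hold no spread between animals.

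Genes were named by a fixed rule. In each comparison and direction these were the 10 genes past 2-fold in both pairs with the largest smaller ratio, among probe sets with 1 symbol whose brighter array was at or above its median signal. Up to 4 members of each list that met the same criteria were added, then any member needed to describe a list, and always Kit, Kitl, Gdnf, Xist, Ddx3y, Eif2s3y, Sox9, Amh, Star and Ddx4. Counts of list members use the deposited signals without a filter. The 5 largest double ratios each way were named. Ranks use the deposited signals, also where the fold is a bound. Clone and predicted-gene names were passed over, 1 in each direction of the preparation comparison and 0 in the genotype comparison. No probe set carried the name Ddx3y, which was not analysed here.

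The alternatives were median centring or quantile normalisation of the arrays, filters on low signals, an offset of 53 (the 25th percentile of all signals) added before the ratio, other fold thresholds, counting genes, single pairs, and the mean over all probe sets of a gene. The 2-fold rule in both preparations was tested on simulated data with 22626 probe sets and the spread of these arrays. In the genotype comparison among signals at or above the median (0 change in 11218 probe sets, of which 10 were called) it called 17 of 21 with a log2 change of 1.5, 26 of 27 with 2, 23 of 23 with 3 and 20 of 24 with -1.5. Over all signals it called 31, 42, 44 and 29 of 50, and 1109 of 22426 without a change. Of simulated lists of 15 genes in the whole testis comparison, 96 of 100 moved by 1 log2 unit were called, and 7 of 100 unmoved lists. Values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9.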

Results

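Gene expression was measured in the testes of adult males of 2 mouse genotypes with Affymetrix 430A oligonucleotide arrays, 4 in all. W/Wv males carry mutations of the receptor tyrosine kinase gene Kit, which leave the testis nearly without germ cells, and are used as recipients for germ cell transplantation. XX/Sry males have a pair of X chromosomes and an Sry transgene, which makes an XX embryo develop testes; such testes also lose their germ cells. Each genotype was measured as whole testis and as seminiferous tubules isolated with collagenase, so that the 4 groups (genotype by preparation) had 1 array each. With 1 array per group there were no replicates, so every fold given here is a ratio of single arrays. The only error came from an additive fit of genotype and preparation, which leaves 1 residual degree of freedom over the 4 arrays and counts any interaction as error. If both preparations of a genotype came from the same animals, that error holds no spread between animals. The strain of the XX/Sry males is not given in the sources used here, so the genotype ratios include any difference of strain. The median signal over the 22626 probe sets was 183 in W/Wv whole testis, 172 in XX/Sry whole testis, 157 in W/Wv tubules and 159 in XX/Sry tubules. The number of arrays limits the precision of all values.

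The genotype labels were checked on the sex chromosomes. Eif2s3y, a Y chromosome gene for a translation initiation factor subunit, had signals of 795 and 580.3 in W/Wv whole testis and tubules, and of 9.5 and 28.2 in XX/Sry, below the background bound there; it was at least 10.4-fold lower in XX/Sry whole testis and at least 9.51-fold lower in XX/Sry tubules. Xist, the noncoding RNA of X inactivation, ran the opposite way, with 131 and 76.7 in W/Wv against 3099 and 1002 in XX/Sry, 23.7-fold and 13.1-fold higher. Of the 7 Y chromosome genes measured, 4 were at least 2-fold lower in XX/Sry in both preparations, 1 was higher and 2 were neither by the deposited signals; set against the background bound, only Eif2s3y and Uba1y were 2-fold lower in both. The list had medians of -2.26 and -1.0 on the log2 scale. Kdm5d was at least 1.93-fold and at least 2.95-fold lower, and Uba1y was 4.79-fold and 2.01-fold lower. The gene that counted as higher, Zfy2, lay below the background bound on all 4 arrays, and Sry lay above it only in XX/Sry whole testis (170.2); Ddx3y was not analysed here. All 4 arrays matched their genotype labels on Eif2s3y and Xist.

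RNA integrity measures and controls were compared between arrays. The ratio of 3' to 5' signal of the Gapdh control was 0.974 in W/Wv whole testis, 0.733 in XX/Sry whole testis, 0.823 in W/Wv tubules and 0.930 in XX/Sry tubules, and that of the actin control 1.74, 1.41, 1.58 and 1.85. The 18 hybridisation spike controls were brighter on the W/Wv tubules array, with a median log2 deviation of 0.46 from the mean of the arrays against -0.09, -0.18 and -0.17 on the others. Pearson correlations of log2 signals across probe sets, which are not independent replicates, lay between 0.884 and 0.910 for the 6 array pairs. The lowest were those of W/Wv whole testis with XX/Sry tubules (0.884) and with W/Wv tubules (0.889).

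The main comparison set XX/Sry against W/Wv, the 2 kinds of recipient male, in each preparation. Of the markers of Sertoli cells, which nurse the germ cells, 37 of 38 did not pass 2-fold in both preparations. Most genes did not pass either: over all 12393 genes 245 were higher and 399 lower. Genes of Leydig cells, which make testosterone, were higher as a list in XX/Sry, with median log2 ratios of 0.69 in whole testis and 0.60 in tubules. Kit, the gene mutated in W/Wv, was 3.48-fold and 4.09-fold higher in XX/Sry. The glandular kallikreins Klk1b24, Klk1b21 and Klk1b27 were between 4.34-fold and 8.78-fold higher. The spermatogonial list had a median of -1.71 in whole testis, called lower in XX/Sry, and of -0.09 in tubules, not called.

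The design text calls a gene different at 2-fold or more in both preparations. By that rule 497 probe sets were higher and 859 lower in XX/Sry, a share of 36.7% higher, which became 39.3% after centring the arrays on their medians and 48.6% (627 higher, 664 lower) after quantile normalisation. If the preparations varied independently within classes of like signal, 375 higher and 747 lower would pass. Among the 25% of probe sets with the lowest mean signal, 895 passed the same way in both preparations and 807 passed in opposite ways; among the 25% with the highest, 72 and 9. With the brighter array of each pair at or above its median signal, 143 probe sets were higher and 82 lower, against 28.1 and 24.9 for independent preparations; the 10 genes named in each direction come from these. With 1 probe set per gene these were 83 higher and 42 lower genes. The median log2 ratio of the spike controls was -0.13 in whole testis and -0.66 in tubules. In the additive fit, tested with limma and chosen after seeing the data, 25 of 22626 probe sets were higher and 9 lower in XX/Sry at an adjusted p under 0.05, all of them 2-fold in both preparations. The named genes among them were Xist, Klk1b24, Klk1b21, Klk1b27, Plbd1, Sult1e1 and Tmem87a, which were higher, and Eif2s3y, Igfbp3 and Rab3b, which were lower; Kit had an adjusted p of 0.0525.

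**Figure D1:**
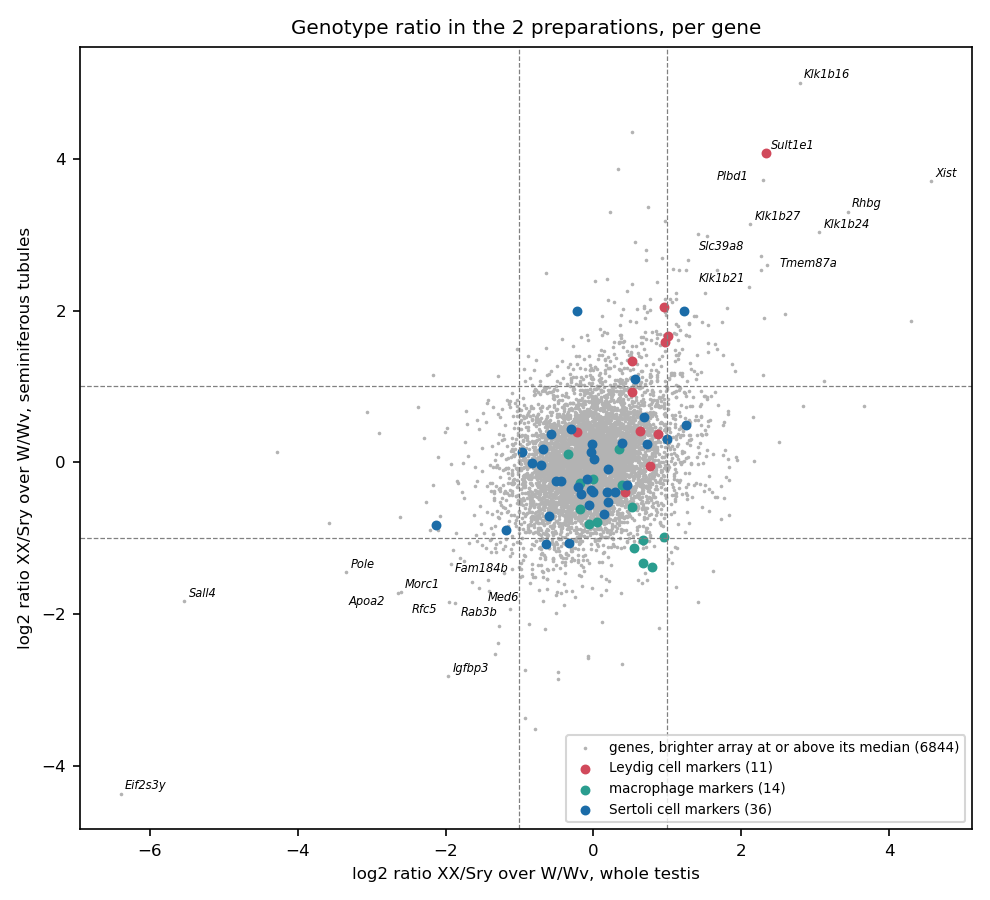
Log2 ratio of XX/Sry over W/Wv signal in seminiferous tubules (vertical axis) against that in whole testis (horizontal axis), 1 point per gene for 6844 genes whose brighter array was at or above its median signal in both preparations; dashed lines mark 2-fold, colours mark Leydig, macrophage and Sertoli markers, and the named genes are written beside their points. Xist lies at 4.57 and 3.71 and Klk1b24 at 3.05 and 3.04, while Eif2s3y, below the background bound in XX/Sry, is drawn at its deposited signals.

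The 10 genes highest in XX/Sry in both preparations, ranked by the deposited signals, were Xist, Rhbg, Klk1b24, Klk1b16, Tmem87a, Sult1e1, Plbd1, Slc39a8, Klk1b21 and Klk1b27. Klk1b24 had signals of 2159 and 444.5 in W/Wv whole testis and tubules and of 17868 and 3652 in XX/Sry, 8.28-fold and 8.22-fold higher. Klk1b21 was 4.81-fold and 5.80-fold higher, Klk1b27 4.34-fold and 8.78-fold, and Klk1b16 6.89-fold and at least 3.79-fold; these serine protease genes are near-identical copies, so their probe sets may share transcripts and the members cannot be counted as separate. Sult1e1, the estrogen sulfotransferase of Leydig cells, was 5.05-fold and 16.9-fold higher. Plbd1, a phospholipase B domain gene, was 4.87-fold and 13.2-fold higher, Tmem87a 5.06-fold and 6.06-fold, the metal ion transporter gene Slc39a8 at least 3.57-fold and 6.59-fold, and the ammonium transporter gene Rhbg at least 5.11-fold and at least 3.89-fold.

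The 10 genes lowest in XX/Sry by the deposited signals were Eif2s3y, Igfbp3, Rab3b, Rfc5, Sall4, Apoa2, Morc1, Fam184b, Med6 and Pole. Igfbp3, a binding protein of insulin-like growth factors, was 3.89-fold lower in whole testis and 7.05-fold lower in tubules, and the small GTPase gene Rab3b 3.67-fold and 3.61-fold. The germ cell genes Sall4 and Morc1 were at least 5.03-fold and at least 2.66-fold lower, and 6.08-fold and 3.26-fold lower; a further Sall4 probe set did not pass. The DNA replication genes Rfc5 and Pole were 3.86-fold and at least 2.94-fold lower, and at least 4.17-fold and 2.73-fold lower. The ranks of genes whose fold is given as a bound are not fixed. Apoa2 was at least 3.54-fold and 3.29-fold lower, Fam184b 3.14-fold and 2.99-fold, and Med6 2.92-fold and 3.15-fold.

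Of the 14 Leydig cell markers measured, 2 were at least 2-fold higher in both preparations (Sult1e1 and Hsd17b3) and 12 were neither, while 12 had a ratio above 0 in whole testis and 11 in tubules. The list median exceeded 100% and 99.97% of 10000 random lists of like signal. Hsd17b3, which makes testosterone from androstenedione, was 2.02-fold and 3.16-fold higher. Hsd3b1 had signals of 7322 in W/Wv and 14284 in XX/Sry whole testis and of 1389 and 4172 in tubules, 1.95-fold and 3.0-fold higher. Cyp17a1 was 1.43-fold and 2.53-fold higher, and Star, the cholesterol carrier of steroid synthesis, 1.44-fold and 1.90-fold. Hsd3b3, a close copy of Hsd3b1 outside the list, went the opposite way. Its signals were 916 in W/Wv and 219 in XX/Sry whole testis, and 142 and 30 in tubules, the last below the background bound. The 18 cholesterol synthesis genes were also higher as a list, with medians of 0.51 and 0.34, though 0 of them passed 2-fold in both preparations; Fdft1 was 1.70-fold and 2.07-fold higher. The tubule call of that list was lost when all probe sets of a gene were averaged (median 0.21, percentile 96.2).

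**Figure D2:**
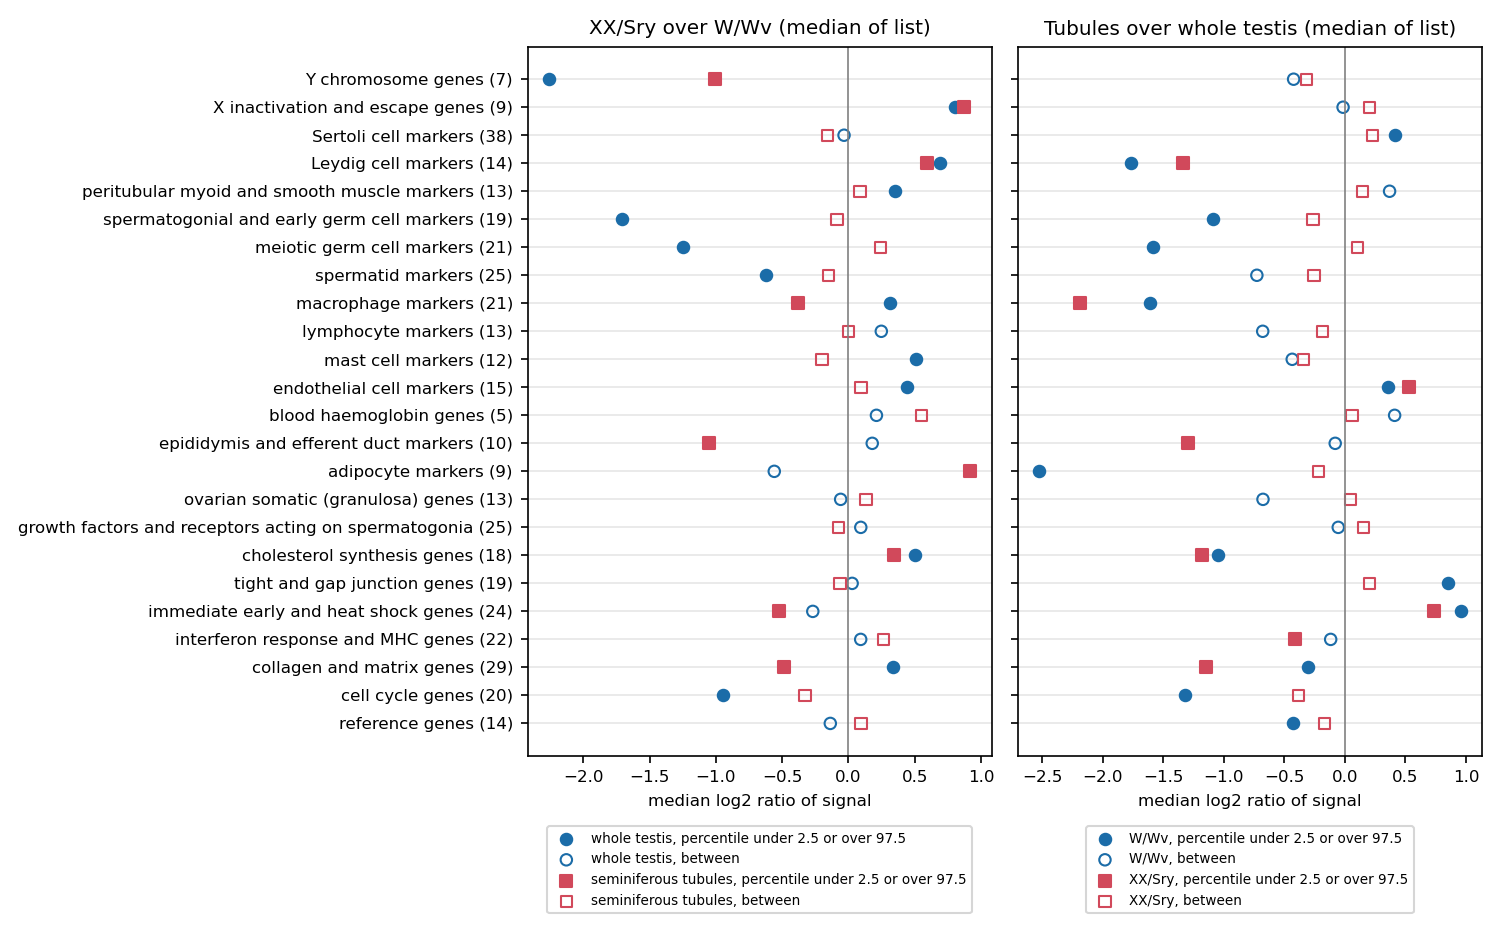
Median log2 signal ratio (horizontal axes) of each of the 24 gene lists (vertical axis, number of measured genes in brackets), for XX/Sry over W/Wv on the left and tubules over whole testis on the right; circles and squares are the 2 preparations or genotypes, filled where the median lay outside the percentile bounds of random lists of like signal. The Leydig list lies at 0.69 and 0.60 on the left and at -1.77 and -1.33 on the right.

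Kit, on chromosome 5, had signals of 256 and 139 in W/Wv whole testis and tubules and of 892.5 and 569 in XX/Sry. Its ligand gene Kitl, made by Sertoli cells, differed little, with 3616 and 5119 in W/Wv against 3214.5 and 3852 in XX/Sry (log2 ratios of -0.17 and -0.41). Gdnf, the Sertoli cell factor that keeps spermatogonial stem cells, was at least 2.84-fold lower in XX/Sry whole testis and 1.77-fold lower in tubules, and so did not pass in both. Sox9, a transcription factor of Sertoli cells, was 1.05-fold and 1.48-fold lower (0.02 on the log2 scale in whole testis after median centring), and Amh lay near background, with signals of 8.6 and 78.2 in W/Wv and 51.8 and 64.2 in XX/Sry. The 38 Sertoli markers had medians of -0.03 and -0.16, at percentiles of 44.7 and 3.78. The whole testis median was 0.06 after median centring; the tubule median was 0.00 after quantile normalisation (percentile 51.2) and was called lower with the mean of all probe sets (-0.23, percentile 1.03). Wnt5a, the member that passed, was 2.33-fold and 3.98-fold higher. Among 25 growth factor and receptor genes acting on spermatogonia (medians 0.09 and -0.07, not called, though 0.30 at percentile 99.4 in whole testis with the mean of all probe sets), 2 were higher, 2 lower and 21 neither by the deposited signals, and Vegfa alone had a bright enough signal to be named; it was at least 2.48-fold and 3.59-fold higher.

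Germ cell lists were called lower in XX/Sry in whole testis, with medians of -1.71 for 19 spermatogonial, -1.25 for 21 meiotic and -0.62 for 25 spermatid genes. In tubules the medians were -0.09, 0.24 and -0.15, without a call, and the difference between preparations was not tested. Ddx4, the germ cell helicase, had a signal of 304.8 in W/Wv whole testis and 0.9 in XX/Sry whole testis, at least 3.99-fold lower, against 69.2 and 1.8 in tubules, at least 1.13-fold lower. Prm1, a protamine of spermatids, had 1546 in W/Wv whole testis, 99.0 in XX/Sry whole testis, 23.8 in W/Wv tubules and 155.5 in XX/Sry tubules. Tnp1 had 814 in W/Wv whole testis and at most 29.5 on the other arrays. Many members lay below the background bound on 3 of the arrays, so the medians hold ratios that are bounds; after adding a constant of 53 to all signals they were -1.02, -0.70 and -0.30, and the spermatid list lost its call (percentile 7.47). Of the 3 lists, 4, 3 and 5 members were lower in both preparations, and Kit was the only member higher; none of the lower members had a brighter array at or above its median in both preparations, and against the background bound 2-fold in both is not established for members such as Ddx4. The list of 20 cell cycle genes was called lower in whole testis (median -0.95), with 4 members lower in both preparations and 16 neither. Its median was -0.33 in tubules (percentile 3.80, but called at -0.54 with the mean of all probe sets), and Cdc20 was 3.38-fold and 2.47-fold lower.

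Among the remaining lists, the list of 9 X inactivation and escape genes was called higher in both preparations (medians 0.80 and 0.87), with 8 of 9 ratios above 0 in each preparation, 1 member past 2-fold in both and 8 neither. Besides Xist, which passed, Kdm6a was 2.35-fold and 1.88-fold higher and Eif2s3x 1.74-fold and 1.90-fold. Macrophage markers had medians of 0.32 in whole testis and -0.38 in tubules, and collagen and matrix genes of 0.34 and -0.48, called on opposite sides in the 2 preparations. Endothelial (0.44), peritubular myoid (0.35) and mast cell markers (0.51) were called higher in whole testis, against 0.10, 0.09 and -0.20 in tubules without a call and Emcn of the endothelial list was 2.56-fold and 2.29-fold higher. The mast cell call was lost after quantile normalisation (0.73, percentile 96.9) and the peritubular call over members of at least median signal (0.35, percentile 97.2). In tubules and not in whole testis, adipocyte markers were called higher (0.92, against -0.56 in whole testis), and epididymis markers (-1.05, against 0.18) and immediate early and heat shock genes (-0.53, against -0.27) lower; for none of these lists was the difference between preparations tested. The spike controls had a median of -0.66 in tubules, so a factor on an array could make the direction of the immediate early list there. Its place among random lists does not depend on such a factor. The adipocyte call was lost with the mean of all probe sets (0.71, percentile 95.3), and immediate early genes were called lower in whole testis too with that mean (-0.34, percentile 1.21) and over members of at least median signal (-0.33, percentile 2.06). Scd1, a fatty acid desaturase of the adipocyte list, was 2.22-fold and 2.72-fold higher. Lymphocyte markers (0.25 and 0.00), haemoglobin genes (0.21 and 0.55), ovarian somatic genes (-0.06 and 0.13), tight and gap junction genes (0.03 and -0.06), interferon and MHC genes (0.09 and 0.26) and reference genes (-0.14 and 0.10) were called in neither, except that tight and gap junction members of at least median signal were called lower in tubules (-0.34, percentile 1.29).

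**Figure D3:**
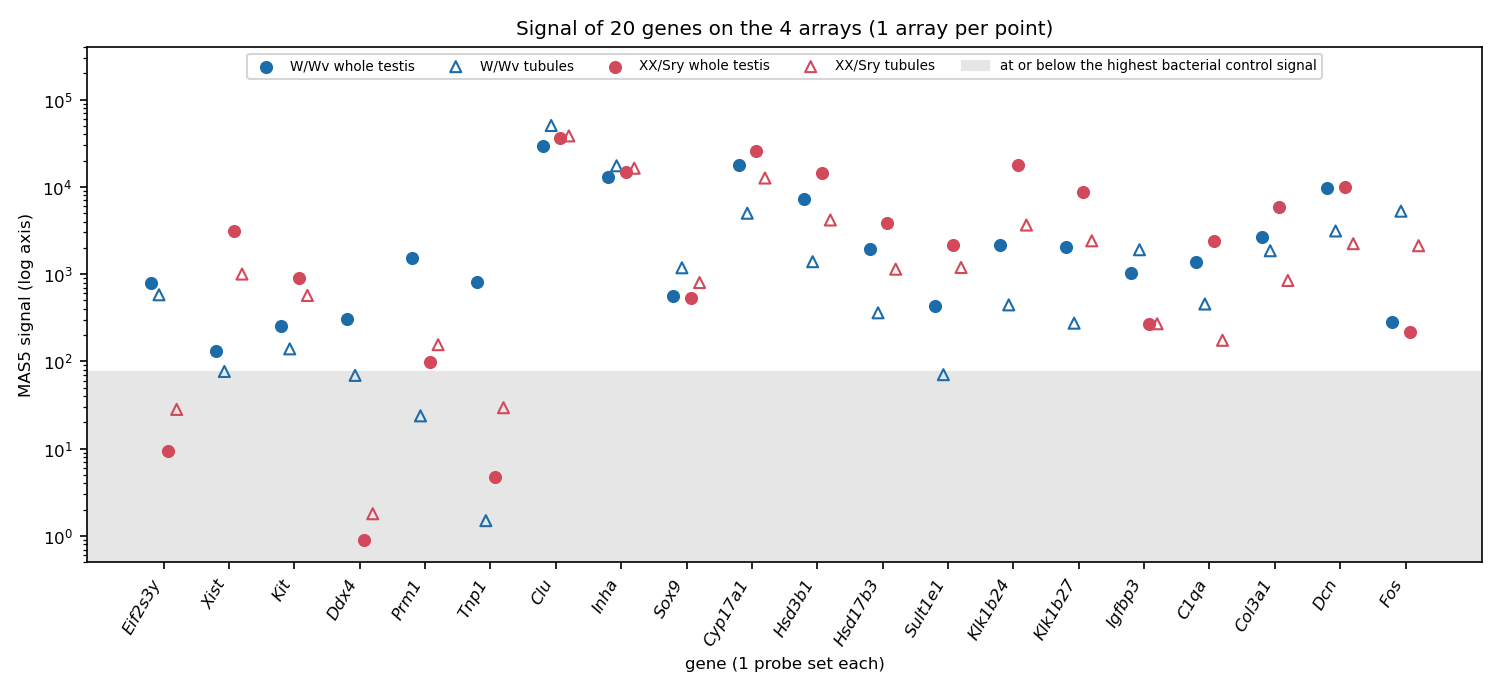
MAS5 signal (vertical axis, log scale) of 20 genes (horizontal axis, 1 probe set each, chosen after their values were seen) on the 4 arrays, with filled circles for whole testis, open triangles for tubules, blue for W/Wv and red for XX/Sry; the grey band reaches up to the highest bacterial control signal. Prm1 and Tnp1 stand at 1546 and 814 in W/Wv whole testis, and Tnp1 lies in the band on the other 3 arrays.

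The ratios of several named genes stood close to the rule: Wnt5a, Hsd17b3, Emcn, Scd1, Sall4 and Cdc20 fell under 2-fold in at least 1 preparation under some other scaling, offset or choice of probe set. The median log2 ratio of all probe sets was -0.11 in whole testis and -0.02 in tubules.

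The other comparison set isolated tubules against whole testis within each genotype, in which digestion, straining and any difference between animals enter together. Leydig cell and macrophage lists, both of cells between the tubules, were called lower in tubules: the Leydig list had medians of -1.77 in W/Wv and -1.33 in XX/Sry, and the macrophage list -1.61 and -2.19. Cyp11a1, which starts steroid synthesis, was 5.08-fold and 5.87-fold lower, and the macrophage gene C1qb 4.56-fold and 7.29-fold. Fos, a transcription factor gene induced within minutes by many stimuli, was 18.6-fold and 9.79-fold higher in tubules. Most Sertoli markers passed in neither direction: 3 of 38 were higher and 1 was lower. Over all 12393 genes 163 were higher and 711 lower.

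At 2-fold or more in both genotypes, 409 probe sets were higher and 1326 lower in tubules, a share of 23.6% higher, which became 37.6% after median centring (620 higher, 1030 lower) and 41.2% after quantile normalisation (643 and 918). Independent genotypes would give 310 and 953 within classes of like signal. With the brighter array at or above its median, 126 were higher and 391 lower, against 35.4 and 79.0 for independent genotypes, and 6 and 14 went in opposite ways. With 1 probe set per gene these were 55 higher and 236 lower genes. The spike controls were also higher in W/Wv tubules than in W/Wv whole testis, by a median of 0.56, and differed by 0.00 in XX/Sry. In the additive fit 54 probe sets were higher and 221 lower in tubules at an adjusted p under 0.05, of which 48 and 212 were 2-fold in both genotypes. The named genes that did not reach it were Rnf144a, Sgsm3, Acaca, Plxna1, Suco, Nr0b1, Vwf, Hoxc9, Mfap2, Scd1, Col5a2, Nid2, Cdc20 and Rrm2. The median log2 ratio of all probe sets was -0.15 in W/Wv and -0.03 in XX/Sry.

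The 10 genes lowest in tubules by the deposited signals were Cbr2, Hao2, Tyrobp, Hsd3b3, Hoxc9, Pf4, Apoc1, Mfap2, Fdps and Vegfd. Carbonyl reductase gene Cbr2 was 9.04-fold lower in W/Wv and at least 18.9-fold lower in XX/Sry, the hydroxyacid oxidase gene Hao2 8.10-fold and 8.81-fold, and Tyrobp, a signalling adaptor of myeloid cells, 7.44-fold and 7.88-fold. Pf4 was 5.95-fold and 12.8-fold lower, Apoc1 5.82-fold and 6.19-fold, and Vegfd 5.68-fold and 6.05-fold. Hsd3b3, a close copy of Hsd3b1, was 6.47-fold and at least 3.43-fold lower. In whole testis its signal was 916 in W/Wv and 219 in XX/Sry, while that of Hsd3b1 was 7322 and 14284. In tubules they were 142 and 30 for Hsd3b3, and 1389 and 4172 for Hsd3b1. The opposite directions argue against transcripts shared with Hsd3b1 as the main source of the Hsd3b3 signal. Hoxc9 was at least 2.42-fold and at least 2.78-fold lower, and Mfap2 at least 2.98-fold and at least 4.0-fold; both lay below the background bound in tubules, so their ranks are not fixed. Fdps, an enzyme of cholesterol synthesis, was 5.73-fold and 6.53-fold lower, but the mean with its other probe set turned the XX/Sry log2 ratio from -2.71 to 0.43.

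Of the 14 Leydig markers, 8 were at least 2-fold lower in both genotypes and 6 neither, among them Hsd3b1 (5.27-fold and 3.42-fold lower), Hsd17b3 (5.35-fold and 3.42-fold) and Vcam1 (3.24-fold and 5.65-fold). Of the 21 macrophage markers, 14 were lower and 7 neither; Folr2 was 3.93-fold and 4.10-fold lower and Laptm5 3.69-fold and 7.22-fold. Cholesterol synthesis genes were lower in 9 of 18 (medians -1.04 and -1.18), with Tm7sf2 at 4.44-fold and 5.31-fold, Sc5d at 4.18-fold and 3.27-fold and Idi1 at 4.73-fold and 3.22-fold. A further Sc5d probe set was not lower in both genotypes. Collagen and matrix genes were lower in 4 of 29 (medians -0.31 and -1.14), namely Lum (3.42-fold and 5.93-fold), Dcn (3.08-fold and 4.40-fold), Col5a2 (2.34-fold and at least 4.85-fold) and Nid2 (2.04-fold and 2.57-fold). The growth factor genes Cxcl12 and Igf1 were 2.91-fold and 2.65-fold lower, and 2.42-fold and 6.92-fold lower. Fabp3, a fatty acid binding protein on the Sertoli list, was 5.42-fold and 3.75-fold lower, and Scd1 2.52-fold and 2.06-fold.

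The 10 genes highest in tubules by the deposited signals were Fos, Pdia4, Rnf144a, Plat, Sgsm3, Acaca, Ncstn, Chpf, Plxna1 and Suco. Pdia4, a protein disulfide isomerase of the endoplasmic reticulum, was 4.10-fold and 5.23-fold higher, Plat, tissue plasminogen activator, 3.88-fold and 3.29-fold, and Ncstn, a subunit of gamma-secretase, 4.90-fold and 2.71-fold. Rnf144a was at least 3.02-fold and 3.48-fold higher, Acaca 3.35-fold and 2.76-fold, Sgsm3 2.91-fold and 2.83-fold, Chpf 2.65-fold and 2.95-fold, Suco 2.56-fold and 2.62-fold, and Plxna1 at least 2.29-fold and 2.58-fold. Of the 24 immediate early and heat shock genes, 4 were higher in both genotypes and 20 neither (medians 0.96 and 0.74), with Jun at 3.55-fold and 2.13-fold, Egr1 at 2.12-fold and 3.80-fold and Gadd45b at 2.07-fold and 3.12-fold. Sertoli markers were called higher in W/Wv (0.42, percentile 99.9) and not in XX/Sry (0.23, percentile 91.3), though in XX/Sry too with the mean of all probe sets (0.35, percentile 99.9); the members that passed were Itga6 (2.41-fold and 2.24-fold), Cdh2 (2.12-fold and 3.53-fold) and Nr0b1 (2.14-fold and 2.02-fold). Endothelial markers were higher as a list (0.36 and 0.53), with 2 of 15 members passing, Vwf among them at least 3.70-fold and 2.23-fold; over members of at least median signal both calls were lost and the XX/Sry median was -0.49. Tpm2, of the peritubular list, was 2.98-fold and 2.18-fold higher.

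In W/Wv and not in XX/Sry, spermatogonial (-1.09, against -0.26 in XX/Sry), meiotic (-1.59, against 0.10), adipocyte (-2.52, against -0.22), cell cycle (-1.32, against -0.38) and reference genes (-0.43, against -0.17) were called lower in tubules, and tight and gap junction genes (0.85, against 0.20) higher. In XX/Sry and not in W/Wv, epididymis markers (-1.30, against -0.08 in W/Wv) and interferon and MHC genes (-0.41, against -0.12) were called lower; these differences between genotypes were not tested. The cell cycle call was lost over members of at least median signal (-0.32, percentile 14.4) and the interferon call with the mean of all probe sets (-0.37, percentile 3.97). The cell cycle genes Cdc20 (3.94-fold and 2.88-fold) and Rrm2 (2.25-fold and 3.72-fold) were lower in both. Neither genotype gave a call for Y chromosome genes (-0.42 and -0.32), X inactivation genes (-0.02 and 0.20), peritubular (0.37 and 0.15), spermatid (-0.73 and -0.25), lymphocyte (-0.68 and -0.18) and mast cell markers (-0.43 and -0.34), haemoglobin (0.41 and 0.06), ovarian somatic (-0.68 and 0.05) or growth factor genes (-0.05 and 0.15). In W/Wv the peritubular list was called higher after quantile normalisation (0.52, percentile 99.1), with the offset (0.35, percentile 97.6) and with the mean of all probe sets (0.37, percentile 97.6), and the spermatid list lower with the offset (-0.52, percentile 1.90). Pdia4, Plxna1, Nr0b1, Tpm2, Vwf, Jun, Gadd45b, Scd1, Cxcl12, Col5a2, Nid2 and Rrm2 came under 2-fold in at least 1 genotype under some other scaling, offset or choice of probe set.

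The design crosses genotype with preparation, so the genotype ratio can be set against itself in the 2 preparations. Of 11289 probe sets with a bright enough signal, 173 had genotype ratios at least 4-fold apart, 82 with a higher XX/Sry over W/Wv ratio in tubules and 91 with a lower one, and 24 were at least 2-fold in opposite directions. By the deposited signals the ratio was highest in tubules against whole testis for Wnt4, Nat8f5, Trim62, Sall4 and Ndrg4; for Sall4 both XX/Sry signals lay below the background bound, which fixes no direction. Wnt4, a signalling gene of ovarian development, had 238.9 in W/Wv and 12.3 in XX/Sry whole testis, at least 3.13-fold lower, and 207.9 and 228.9 in tubules. Ndrg4 was 1.26-fold higher in whole testis and 14.6-fold higher in tubules, Nat8f5 1.44-fold and at least 3.49-fold higher, and Trim62 at least 4.14-fold lower and 1.59-fold higher.

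The ratio was lowest in tubules against whole testis for Col1a1, Cldn3, Icosl, Lifr and Sox18. The collagen gene Col1a1 was 2.67-fold higher in XX/Sry whole testis and 3.59-fold lower in XX/Sry tubules. Lifr, the receptor gene of leukaemia inhibitory factor, had 1730 and 5307 in whole testis and 3442 and 1273 in tubules, 3.07-fold higher and 2.70-fold lower. The tight junction gene Cldn3 was 1.84-fold higher and 4.55-fold lower, Icosl 1.31-fold higher and at least 3.12-fold lower, and Sox18, a transcription factor of endothelium, at least 3.89-fold and 1.68-fold higher. A double ratio uses all 4 arrays and leaves no residual for a test; 66 probe sets were past 4-fold after adding 53 to all signals.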

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

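The tests of interstitial removal and of scaling by spike controls below were chosen only after the results were seen. Macrophage markers and collagen genes had a higher median in XX/Sry whole testis and a lower one in XX/Sry tubules: the genotype log2 ratio changed by -0.69 for macrophage markers (from 0.32 to -0.38) and by -0.82 for collagen and matrix genes (from 0.34 to -0.48). Scaling was tested by quantile normalisation, after which the pooled median double ratio of both lists was -0.73, which argues against a scaling that differs with signal as the cause. The spike controls had a double ratio of -0.53 the same way, since they were brighter on the W/Wv tubules array; taking it off leaves -0.16 for the lists, so that for the direction in tubules a factor on that array and a change of these genes cannot be told apart, while the lists' place among random lists does not depend on such a factor. More complete removal of all interstitial tissue from the XX/Sry tubules would have lowered the Leydig markers as far. Their median double ratio was 0.51, with 6 of 14 below 0, against -0.69 for the pooled lists, a difference of 1.20 whose 95% bootstrap interval of -0.09 to 1.54 includes 0, so it cannot be told apart from a change in those cells alone; a difference by genotype or strain stays open and the difference between preparations was not tested.

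Col1a1 stood out because its genotype ratio was above 2-fold in opposite directions in the 2 preparations, with a log2 double ratio of -3.26, and the difference was not tested. Lifr did the same, with -3.05, also not tested. The control probe set for the B1 repeat, a short interspersed element, lies outside the main measurement; it had signals of 31866 in W/Wv whole testis, 6511 in XX/Sry whole testis, 3655 in W/Wv tubules and 1327 in XX/Sry tubules, 4.89-fold and 2.75-fold higher in W/Wv.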

How the results depend on the processing

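The filter by bacterial controls and the additive fit were chosen after seeing the data; the other alternatives were fixed earlier. Counts are given as probe sets higher and lower in XX/Sry, then higher and lower in tubules, against 497, 859, 409 and 1326. They were 302, 330, 244 and 776 with the brighter array at or above its 25th percentile, 143, 82, 126 and 391 at or above its median, and 73, 37, 86 and 211 with the dimmer array also at or above the median. A brighter array above the bacterial controls gave 265, 303, 213 and 708, and an offset of 53 gave 124, 80, 95 and 370. Thresholds of 1.5-fold, 3-fold and 4-fold gave 1198, 1866, 1282 and 2758, then 159, 374, 134 and 534, then 76, 201, 70 and 274. Counting genes gave 245, 399, 163 and 711. The first pair alone gave 2068, 3354, 2107 and 4307, and the second alone 2682, 2737, 2327 and 3375. The additive fit tested with limma gave 25, 9, 54 and 221 at an adjusted p under 0.05, and 890, 1087, 1288 and 1865 at an unadjusted p under 0.05. Filters, thresholds, genes and single pairs admit more or fewer probe sets by construction, and the offset makes ratios smaller; the cause of the counts from the fit was not tested. Probe sets higher in tubules numbered 620 after median centring and 643 after quantile normalisation. The median signal was lower in tubules than in whole testis, 157 against 183 in W/Wv and 159 against 172 in XX/Sry. Median centring therefore raises every ratio of tubules over whole testis and admits more such probe sets by construction. The cause under quantile normalisation was not tested. The other counts under those scalings stayed within 1.5 times. The 173 probe sets past a 4-fold double ratio became 3276 without a filter, 66 with the offset and 28 at 8-fold. Of 96 list medians, 43 were called, and 43, 44 and 46 under quantile normalisation, the offset and the mean of probe sets; median centring moves lists and random lists alike and says nothing about these calls. With members at or above the median signal 29 of 56 were called, and the other lists had too few members left for a median. Of 344 list medians under the alternatives without median centring, 324 kept their side of the bounds, 11 gained a call and 8 lost one. Of the 324, 305 kept their sign and 19, called in neither setting, changed it, with values from -0.32 to 0.48 under the alternative. A called median changed sign once: endothelial markers in tubules over whole testis of XX/Sry were 0.53 and became -0.49 with members at or above the median signal, and the cause was not tested. Of 162 ratios of named genes, 613 values under alternatives kept their side of 2-fold (Sox9 in whole testis changed sign, to 0.02, after median centring), 33 fell under it, 1 passed it and 1 reversed: Fdps in tubules over whole testis of XX/Sry went from -2.71 to 0.43 as the mean of its probe sets, which differ. Germ cell lists depend on signals near background: after the offset the medians in whole testis were -1.02, -0.70 and -0.30 for spermatogonial, meiotic and spermatid genes. The labels give no replicate numbers to pair by; the additive fit, with preparation or genotype as a block, is the only paired analysis made, and no replicate could be left out. Signal over background limits folds of dim genes: in the lowest 25% of mean signals, 895 probe sets passed one way in both preparations and 807 in opposite ways, and folds against signals below the background bound are bounds or not given.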

Other observations

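The tests of germ cells in W/Wv males by tubule values and of the interstitial share, with the lists set against it, were chosen only after the results were seen. Several genes of germ cell development were brightest on the W/Wv whole testis array; they were chosen after their values were seen. Prm2, which packs sperm DNA with Prm1, had signals of 522 in W/Wv whole testis, 47.0 in XX/Sry whole testis, 36.9 in W/Wv tubules and 54.0 in XX/Sry tubules. Ldhc, the lactate dehydrogenase of germ cells, had 536.5, 52.5, 32.0 and 74.6 in the same order, and Stra8, which acts at the entry into meiosis, 352, 56.5, 18.2 and 7.7. Sycp3, of the synaptonemal complex, had 278, 69.7, 49.1 and 79.6. Dazl, which germ cells express from the spermatogonia on, had 1087, 509.6, 510.0 and 433.

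Over 64 germ cell genes without Kit the median log2 ratio of XX/Sry over W/Wv was -1.10 in whole testis, with 52 of 64 below 0. The W/Wv whole testis array also had the highest signal of the B1 repeat control (31866), of the 18S ribosomal RNA control (320.5, against 241 in XX/Sry whole testis, 172 in W/Wv tubules and 74.1 in XX/Sry tubules) and at the 25th percentile (66.8). A nonspecific rise of low signals on the W/Wv whole testis array was tested on 54 genes of other tissues, which had a median of -0.42. The difference was -0.68 (95% bootstrap interval over genes -1.51 to -0.13), which argues against that rise as the whole cause of the genotype ratio. Those 54 genes passed the bounds in other comparisons, so a list of dim genes of other tissues can be called. Their median was -0.86 in W/Wv tubules over whole testis (percentile 2.48), against -1.25 for the germ cell genes. It was 0.37 in XX/Sry over W/Wv tubules (percentile 98.9). Part of the germ cell pattern may therefore come from such a rise. After quantile normalisation the germ cell median was -0.94, which argues against scaling. Germ cells in the W/Wv testes remain a candidate explanation. In tubules the median lay at percentile 46.4 of random lists, with 32 of 64 ratios below 0. Morc1 and Sall4, outside these lists and named for low ratios in both preparations, were also brighter in W/Wv than in XX/Sry tubules. Their signals were 306.5 against 93.9 and 162.1 against 45.6, though a further Sall4 probe set did not pass. Germ cells in 1 W/Wv sample only, germ cells in both and a difference between animals cannot be told apart with 1 array per group.

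The Leydig cell list was higher in XX/Sry in both preparations, and a larger share of interstitial tissue in the XX/Sry samples would raise macrophage markers alike. Leydig exceeded macrophage medians by 0.972 in tubules (95% bootstrap interval over genes 0.595 to 2.05). The macrophage list was itself lower in XX/Sry tubules for a cause left open above. It therefore cannot measure the share in tubules, and no conclusion is drawn from that excess. In whole testis the excess was 0.379 (0.088 to 0.915), which argues against the share as the whole cause there. The endothelial, mast cell and lymphocyte lists were not called lower in tubules in either genotype, so they are poor measures of that share. Leydig exceeded them in tubules by 0.50 (0.01 to 1.40), 0.80 (-0.15 to 1.79) and 0.60 (-0.64 to 1.75). Pooled with macrophage and collagen genes, they were exceeded by 0.81 (0.40 to 1.77). No conclusion is drawn from these values. Part of the whole testis value may still come from a larger interstitial share, since the medians of macrophage (0.32) and collagen genes (0.34) were also above 0. Endothelial (0.44) and mast cell medians (0.51) were above 0 too, but are poor measures of that share. In whole testis the Leydig median exceeded the endothelial one by 0.25 (-0.33 to 0.99), the mast cell one by 0.18 (-0.84 to 1.33) and the lymphocyte one by 0.45 (-0.79 to 1.16). These intervals include 0. After quantile normalisation the smaller of the Leydig medians was 0.580, which argues against scaling. A higher Leydig signal by genotype may be the cause, and these arrays do not separate the number of Leydig cells from expression per cell. The smaller median of 0.595 rests on 1 array per group without a spread between animals, so genotype, strain and animal cannot be told apart.

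A hypothesis set before its result was seen was that genes of the X chromosome outside the fixed X list may be higher in XX/Sry, which have a pair of X chromosomes. Over 200 such genes with a mean signal at or above the median, the median log2 ratio was 0.11 in whole testis and 0.17 in tubules, against -0.03 and -0.01 for random autosomal lists of like signal. The smaller of the percentiles among 10000 random lists was 99.96, which is consistent with a small rise across the chromosome.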
